A study of Mus musculus with 2 samples.

How the data were processed

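Total RNA of mouse neural tube at embryonic day 14.5 was measured in 2 libraries of 1 group, made from 10 ng of RNA each with spike-in RNA added, per the labels. Extraction used a mirVana kit and a general protocol named for Smart-seq, a method for small amounts of RNA, per the labels' protocols. Reads were aligned to mm10 with GENCODE release 4 of the mouse annotation, per the texts deposited with the files. The aligner, the quantifier, their versions and the strand setting are not given in the sources used here. The deposited expected counts are estimated reads per gene or transcript that the authors did not normalise, per the file headers and their unequal sums. The deposited TPM values are transcripts scaled over all rows, spike-ins included, to the same sum in each library, per the file headers and the sums. The deposited FPKM values are scaled by effective length and depth, per the file headers. The deposited percent columns give the share of a gene's TPM in each transcript, per the file headers. The deposited score columns, which are posterior spreads and credibility bounds, were not used. Each library was quantified separately.

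Each gene table held 69691 rows: 43346 genes, 26248 rows with numeric identifiers, 96 spike-ins and phiX. Library sizes and list statistics used the gene rows. Symbols and types came from GENCODE release 21 for GRCm38, the assembly that mm10 names, by identifier without version, and coordinates are 1-based from that release. Of the gene rows, 42462 matched and 884 did not. Of symbols found on more than 1 row (20 symbols), the row with most counts was used. Before the data were examined, 41 gene lists with 430 entries, the comparisons, the alternatives and the rule for named genes were fixed. Of the list entries, 3 had no row (Ahsp, Rmst, Sox2ot). The rule named the 4 highest members of each list and members under 1 TPM that bear on a comparison, the 15 protein-coding genes outside the mitochondrial genome with the highest mean TPM, the 10 largest ratios in each direction at a mean count of at least 100, Hox genes by paralogue group, Xist and the Y-linked genes. Some genes that the rule names are not reported here, though the list statistics include them. Igf2, H19, Hbb-y, Hba-x, Hoxc8, Hoxb8, Hoxd8 and Hoxd1 fall outside the rule and were chosen after their values were seen. After the first results, 4 lists with 34 entries were added for the tests of explanations, without their own values.

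Expected counts were rounded to whole numbers. The ratio of replicate 2 to replicate 1 used TMM-scaled library sizes from edgeR 4.0.16 (R 4.3.3) with a prior count of 0.5. List ratios are medians over members with a mean count of at least 10, set beside 10000 random lists drawn member by member from the 200 genes nearest in mean count. Intervals for single genes are exact (Clopper-Pearson, 95%) on the counts of the pair. They and the floor of 3 counts cover counting error only, since reads from amplified RNA are not independent molecules. The biological coefficient of variation is the square root of edgeR's common dispersion with an intercept alone, and DESeq2 1.42.0 gave alternatives. Other steps used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. In counts simulated for the comparison of replicate 2 with replicate 1 with a coefficient of variation of 0.2, edgeR returned 0.1995 over 17171 unchanged genes and 0.215 over 17366 genes, changed ones included. The other steps ran on 17610 genes, 200 of them changed. Of genes changed 2-fold, 91.1% passed 1.5-fold, and of those changed 4-fold, 100%. Of 100 unchanged lists, 93 lay within the central 95% of their random lists. The simulated genes varied independently of each other, so this does not show how often lists of genes that vary together fall outside. Alternatives covered thresholds, pseudocounts, count filters, FPKM and posterior mean TPM, DESeq2 size factors, spike-in scaling and each library alone.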

Results

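The deposited data profile total RNA of the mouse neural tube, the embryonic structure that forms the brain and spinal cord, at embryonic day 14.5 in the B6NCrl strain. There was 1 group of 2 libraries. The labels describe replicate 1 as the tube of pup 1 of pregnant female 1 and replicate 2 as that of pup 1 of pregnant female 2, each made from 10 ng of RNA, and they also give the sex as male and female pooled. With a single group no contrast between conditions exists, and 2 libraries cannot give an exact test below a p of 0.05. Levels are therefore given as mean TPM ± SD of the 2 libraries (n = 2), and differences between the libraries describe these 2 libraries, with no p-value. Expected counts totalled 33360108 in replicate 1 and 26025302 in replicate 2. Of 43346 gene rows, 15053 reached 1 TPM in both libraries, 13047 of them protein-coding. A further 778 reached it in replicate 1 alone and 901 in replicate 2 alone. Across genes, which are not independent replicates, log2(TPM + 1) had a Pearson r of 0.987 and a Spearman rho of 0.943. The biological coefficient of variation was 0.262 over 17623 genes, from 0.434 in the bin of mean counts from 10 to 0.137 in the bin from 3000 and 0.225 in the bin from 10000. Without the 5% of genes that differed most, an alternative chosen after seeing the data that lowers it by construction, it was 0.155 over 16743 genes. It was 0.0732 by DESeq2's median gene-wise dispersion.

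**Figure D1:**
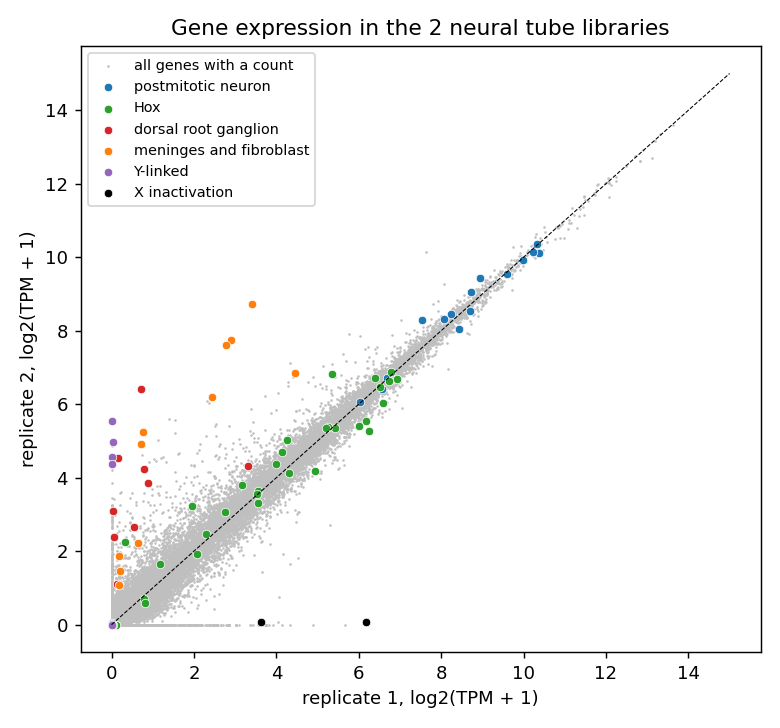
Each grey point is a gene with at least 1 count, at its log2(TPM + 1) in replicate 1 (x axis) and replicate 2 (y axis), with 6 gene lists in colour and a dashed line of equality. Neuron genes and most Hox genes lie near the line, ganglion, meningeal and expressed Y-linked genes above it, and Xist and Tsix, at 70.8 and 0.05 and at 11.4 and 0.05 TPM, below it.

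The median gene of the postmitotic neuron list was expressed far above the median gene of the list of dividing neural progenitors. The median of the neuron list was 392 ± 27.4 TPM and all 15 members passed 1 TPM in both libraries. Its highest members were Tubb3, a neuronal tubulin (1299.7 ± 11.4), Stmn3 (1208 ± 152), the growth cone protein gene Gap43 (1162 ± 47.6) and Stmn2 (992 ± 39.9). The progenitor list had a median of 18.9 ± 3.46 TPM. It was led by the radial glial fatty acid binding protein gene Fabp7 (1792 ± 28.9), Vim (439.6 ± 87.1), the glutamate transporter gene Slc1a3 (174 ± 17.1) and Msi1 (44.4 ± 1.17), while Sox1 (0.83 and 0.76) and Sox3 (0.53 and 0.48) stayed under 1 TPM. The neuron list exceeded the progenitor list by 4.57 in replicate 1 and 4.07 in replicate 2 on the log2(TPM + 1) scale. The SD between the libraries was 0.35, which does not measure the spread across the genes of either list. With means for medians the gap was 3.84. The highest progenitor gene, Fabp7, lay above every member of the neuron list. Genes of the step from progenitor to neuron had a median of 7.04 ± 0.233 TPM, led by Hes6 (81.0 ± 2.59), Btg2 (19.9 ± 3.01), Neurod1 (19.2 ± 0.707) and Dll3 (17.5 ± 0.156). Neurog1 and Atoh1, proneural factors, stayed under 1 TPM in both.

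**Figure D2:**
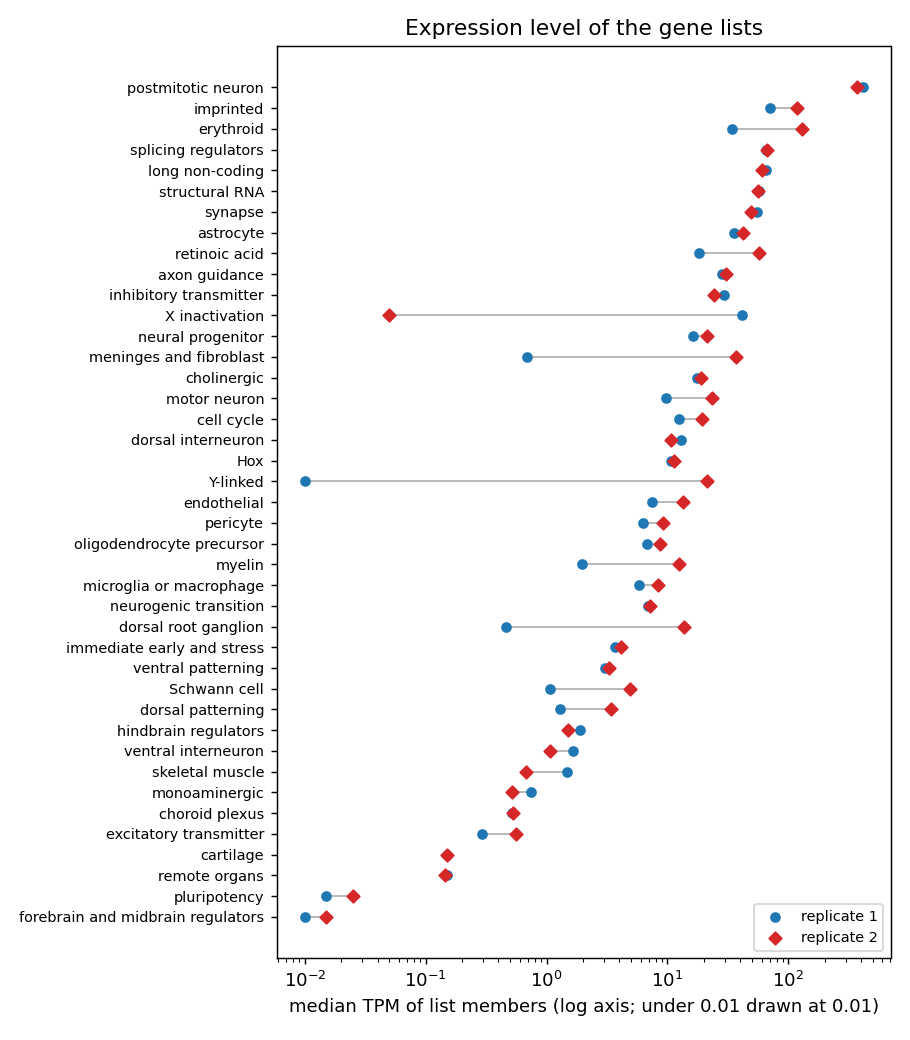
Points are the median TPM of the members of each of the 41 gene lists (x axis, log scale, values under 0.01 drawn at 0.01) in replicate 1 (circles) and replicate 2 (diamonds). The neuron list is highest, at 412 and 373 TPM, the forebrain and midbrain regulators are lowest on average, and the sex-linked, ganglion and meninges lists lie farthest apart.

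Among protein-coding nuclear genes Tuba1a, the alpha-tubulin of migrating and growing neurons, had the highest mean TPM, at 12568 ± 234 TPM (ENSMUSG00000072235.5, chromosome 15, 98949837 to 98953703, GRCm38). It was followed by Actb (5727 ± 25.7), the alpha-globin gene Hba-a2 (4581 ± 379.6), Stmn1 (4406 ± 224), Tmsb10 (4236 ± 344), Ftl1 (4093 ± 77.8), Tmsb4x (3819 ± 336) and Ubb (3559 ± 143). Actg1 (3374 ± 74.8), Ppia (3345 ± 63.0), Eef1a1 (3036 ± 298), Calm2 (2710.1 ± 129.7), H3f3a (2598 ± 72.3), the imprinted gene Nnat (2555 ± 379) and Hspa8 (2445 ± 174) completed the highest 15. Tuba1a, Actb, Actg1, Ppia, Eef1a1, Ubb, H3f3a, Ftl1 and the globin genes have close copies or pseudogenes, so the authors' counting may have divided their reads, and their levels are uncertain.

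Hox genes, which mark position along the trunk, summed to over 1 TPM in both libraries for each paralogue group from 1 to 10, and regulators of the forebrain and midbrain were near or under 1 TPM. Mean summed TPM was highest for paralogue group 9 (263 ± 23.3), then group 7 (195 ± 9.56), group 8 (173 ± 27.0), group 10 (167 ± 60.2) and group 6 (148 ± 17.1). The sums run over 4 genes in group 9, 2 in group 7 and 3 each in groups 6, 8 and 10, so their order need not hold per gene. It was 67.3 ± 8.84 for group 5, 26.3 ± 4.09 for group 4, 31.5 ± 0.636 for group 3, 44.3 ± 3.95 for group 2 and 3.31 ± 2.21 for group 1. The order differed by library, as group 10 lay above group 7 in replicate 1 (209.56 against 188.37) and below group 6 in replicate 2 (124.41 against 160.28). Groups 11, 12 and 13, of the most caudal trunk, summed to 0.085 ± 0.0778, 0.01 ± 0.0141 and 0.015 ± 0.0212, from at most 8 counts in a library. The highest members were Hoxb6 (113 ± 4.14), Hoxa9 (112 ± 14.3), Hoxb7 (102 ± 4.87) and Hoxa7 (93.3 ± 14.4). Of 16 forebrain and midbrain regulators, 15 stayed under 1 TPM in both libraries. Among them were Tbr1 (0.145 ± 0.0212), Dlx1 (0.145 ± 0.205) and Emx1 (0.085 ± 0.12), and Emx2 and Eomes had 0 counts, which allows up to 3 counts per library. The Hox list exceeded these regulators by 3.54 in replicate 1 and 3.62 in replicate 2, with an SD of 0.05, and by 6.71 with a pseudocount of 0.1. Among hindbrain regulators Gbx2 (23.0 ± 2.59) and Phox2a (1.70 ± 0.283) passed 1 TPM, Egr2 (0.45 and 0.84) did not, and the list median was 1.70 ± 0.283. Between the libraries, group 10 was 0.561 [0.539 to 0.584] times as high in replicate 2, with 95% counting intervals in square brackets, group 8 1.23 [1.18 to 1.28] times and group 1 2.88 [2.11 to 3.99] times. Group 9 was at 0.833 [0.809 to 0.857] times, which turns to above 1 under spike-in scaling. Groups 2 to 7 lay between 0.986 and 1.16 times, and under spike-in scaling group 3, the lowest of them, turns to above 1. In group 8 the excess came from Hoxc8 alone, at 2.54 [2.39 to 2.70] times, while Hoxb8 was at 0.693 [0.652 to 0.736] and Hoxd8 at 0.813 [0.733 to 0.901], both of which turn to above 1 under spike-in scaling. In group 1 it came from Hoxd1 alone, with 9 and 99 counts.

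**Figure D3:**
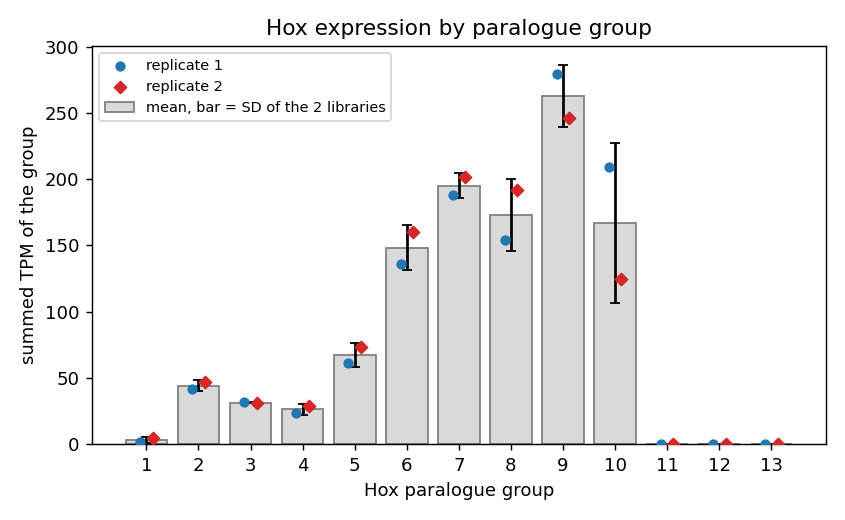
Bars are the mean summed TPM (y axis) of each Hox paralogue group (x axis) over the 2 libraries, error bars the SD, and points the libraries. Summed expression reaches 263 TPM at group 9 and is near 0 from group 11 on, and the groups hold unequal numbers of genes.

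Inhibitory and excitatory transmitter genes were both expressed. The GABA-synthesis genes Gad1 and Gad2 had 80.9 ± 17.8 and 26.8 ± 3.37 TPM, the glycine transporter gene Slc6a5 12.2 ± 1.04 and the vesicular transporter gene Slc32a1 8.0 ± 0.636. Of the vesicular glutamate transporter genes, Slc17a6 had 96.0 ± 7.04 TPM, while Slc17a7 (0 and 0.56) and Slc17a8 (0.29 and 0.11) stayed under 1. The list medians were 26.8 ± 3.37 and 0.425 ± 0.191 TPM, and the log2 difference of 4.55 in replicate 1 and 4.03 in replicate 2 rests on a list with 2 of 3 members under 1 TPM. With means for medians it was 2.54. The cholinergic list had a median of 18.3 ± 1.13 TPM, with Ache at 56.6 ± 8.61, Slc18a3 at 25.7 ± 1.27, Slc5a7 at 10.8 ± 0.997 and Chat at 2.94 ± 0.0424. In the monoaminergic list (median 0.635 ± 0.163), the tyrosine hydroxylase gene Th had 1.31 and 22.4 TPM, Slc18a2 8.14 and 9.07, Ddc 2.16 and 2.88 and Slc6a4 0.75 and 0.52 in replicates 1 and 2. The ganglion list, with a median log2 ratio of 4.95, was higher in the same library as Th. The synapse list had a median of 52.4 ± 4.36 TPM with all 15 members detected, led by Vamp2 (290.1 ± 20.4), the glutamate receptor gene Gria2 (194 ± 46.6), Syp (92.0 ± 36.2) and Syn1 (76.0 ± 5.22). Axon guidance genes had a median of 29.3 ± 1.65, with Robo2 (131 ± 7.28), Nrp1 (60.2 ± 18.2), Slit2 (56.9 ± 10.1) and Slit1 (35.5 ± 7.20) highest.

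Transcription factors of spinal interneurons were detected at lower levels. The dorsal interneuron list had a median of 11.8 ± 1.54 TPM, led by Pou4f1 (68.4 ± 3.89), Lhx1 (38.5 ± 0.339), Tlx3 (29.8 ± 5.32) and Lhx5 (23.0 ± 0.863), and the ventral interneuron list 1.36 ± 0.424, with Gata3 (8.74 ± 2.64), Sox14 (6.99 ± 0.771) and Gata2 (3.56 ± 0.516) among its highest members. Dorsal patterning genes had a median of 2.36 ± 1.52 TPM, 1.29 in replicate 1 and 3.435 in replicate 2. Their median log2 ratio was 0.45, at percentile 98.33 of random lists. Zic1 (23.8 ± 0.488), Olig3 (12.9 ± 0.233), Msx1 (9.77 ± 0.608) and Zic2 (6.38 ± 1.78) were highest, and Pax7, Lmx1a, Gdf7, Wnt3a and Msx2 were under 1 TPM in both. Ventral patterning genes had a median of 3.14 ± 0.166, with the Hedgehog receptor gene Ptch1 (16.7 ± 0.799), Olig2 (6.18 ± 0.955), Nkx2-2 (5.98 ± 0.919) and Nkx6-2 (4.63 ± 0.141) highest, and Shh at 0.55 and 0.72. The dorsal list differed from the ventral list by -0.81 in replicate 1 and 0.06 in replicate 2, so the libraries did not share a direction. The motor neuron list had a median of 16.5 ± 9.50 TPM (9.82 in replicate 1 and 23.26 in replicate 2), led by Prph (53.2 and 239 in replicates 1 and 2), Foxp1 (41.2 and 55.1), Isl1 (23.6 and 70.2) and Aldh1a2 (9.50 and 57.5). Its median log2 ratio of replicate 2 to replicate 1 was 0.23, and the dorsal root ganglion and meninges lists differed in the same direction, by 4.95 and 4.16.

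Most astrocyte, oligodendrocyte precursor and myelin genes on the lists reached 1 TPM in both libraries. Astrocyte genes had a median of 38.8 ± 4.45 TPM, with Sparcl1 (276 ± 25.9), Aldoc (242 ± 54.7), Nfib (90 ± 3.08) and Gja1 (59.2 ± 42.0) highest, and the mature marker Gfap under 1 TPM (0.7 and 0.13). All 8 oligodendrocyte precursor genes passed 1 TPM (median 7.71 ± 1.36), led by Olig1 (44.8 ± 6.41), Ptprz1 (32.2 ± 0.693), Pdgfra (13.2 ± 5.93) and Sox10 (8.96 ± 4.05). Myelin genes had a median of 1.97 TPM in replicate 1 and 12.5 in replicate 2, with Cnp (32.5 and 40.3), Cldn11 (1.64 and 47.5), and Mbp (19.6 and 27.0) among the highest. The precursor list differed from the myelin list by 1.39 in replicate 1 and -0.42 in replicate 2, so no direction was shared. Cldn11 and Sox10 are also expressed outside the central nervous system, and the Schwann cell and meninges lists were higher in replicate 2 as well.

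Sex-linked transcripts differed in opposite directions between the libraries. Xist, the RNA that coats the inactive X chromosome (ENSMUSG00000086503.3, chromosome X, 103460366 to 103483254, GRCm38), had 25148 counts and 70.8 TPM in replicate 1 and 13 counts and 0.05 TPM in replicate 2. It was 1524-fold [891 to 2862] higher in replicate 1, with the 95% counting interval in square brackets, as elsewhere. Its antisense gene Tsix (11.4 and 0.05 TPM) was 255-fold [87.2 to 1241] higher in replicate 1, but it overlaps Xist, the strand setting is not stated and their reads may be shared. The Y-linked genes had the opposite distribution. Eif2s3y, Kdm5d and Uty had 0 counts in replicate 1 and 45.9, 22.4 and 19.7 TPM in replicate 2, which is at least 419-fold, 503-fold and 383-fold higher against a floor of 3 counts per library. Ddx3y had 0.02 and 30.6 TPM, with 1 count in replicate 1 and 1750 in replicate 2. Usp9y and Zfy1 had at most 2 counts in either.

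Genes of tissue that adjoins the neural tube made up the largest list differences between the libraries apart from the sex-linked lists. All 9 members of the dorsal root ganglion list, sensory neurons beside the cord, were over 2-fold higher in replicate 2, and the list median was 0.46 TPM in replicate 1, where 1 member reached 1 TPM, and 13.6 in replicate 2. Avil was 166-fold [80.2 to 414] higher (ENSMUSG00000025432.7, chromosome 10, 127000709 to 127020994, GRCm38), P2rx3 31.8-fold [19.9 to 54.2] and the sodium channel gene Scn9a 2.34-fold [2.18 to 2.51]. All 11 members of the meninges and fibroblast list were over 2-fold higher as well (medians 0.69 and 36.6 TPM). The collagen genes Col3a1, Col1a2 and Col1a1 were 48.5-fold [44.9 to 52.6], 33.3-fold [30.8 to 36.1] and 32.1-fold [29.7 to 34.7] higher, and Dcn 5.14-fold [4.75 to 5.58]. Of 7 Schwann cell genes, 5 were at least 1.5-fold higher, Sox10, which oligodendrocyte precursors also express, by 1.82-fold [1.58 to 2.10] and Erbb3 by 4.27-fold [3.50 to 5.25], whereas Gap43, which neurons also express, had a ratio of 0.885, which turns to above 1 under spike-in scaling. The median log2 ratios of these lists, 4.95, 4.16 and 2.09, exceeded those of all 10000 random lists matched on expression. With deposited TPM the Schwann cell value was 0.95. Egr2, with 4 and 36 counts in replicates 1 and 2, had 0.45 and 0.84 TPM, so its ratio was much smaller by TPM than by counts.

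All 9 endothelial genes, 8 of 12 microglia or macrophage genes and 3 of 7 pericyte genes were at least 1.5-fold higher in replicate 2. The endothelial list (median 10.4 ± 4.29 TPM) had a median log2 ratio of 1.09, above all 10000 random lists, with Cldn5 2.36-fold [2.18 to 2.56], Kdr 2.33-fold [2.17 to 2.51], Esam 1.68-fold [1.51 to 1.86] and Pecam1 1.90-fold [1.68 to 2.15] higher. The pericyte list (median 7.71 ± 2.01 TPM) had a median log2 ratio of 0.46, at percentile 99.10, and its highest members were Rgs5 (15.2 and 20.1 TPM in replicates 1 and 2), Pdgfrb (6.80 and 14.5), Kcnj8 (7.30 and 10.7) and Notch3 (6.29 and 6.40), the last with a ratio of 0.955 that turns to above 1 under spike-in scaling. The microglia or macrophage list (median 7.12 ± 1.87) had 0.64, at percentile 99.92, and its highest members were C1qb (22.3 and 40.7), Tyrobp (18.4 and 32.8), C1qa (15.5 and 23.9) and C1qc (12.1 and 20.6). Skeletal muscle genes were lower in replicate 2. Their median log2 ratio was -1.18, lower than in all 10000 random lists, and 9 of 10 measured members were at least 1.5-fold higher in replicate 1, among them Acta1, 2.61-fold [2.17 to 3.16], Mylpf, 1.84-fold [1.27 to 2.71], Actc1, 1.91-fold [1.49 to 2.47] and Tnnt3, 2.15-fold [1.30 to 3.68]. Cartilage (median 0.15 ± 0 TPM), choroid plexus (0.52 ± 0.00707) and remote organ genes (0.147 ± 0.00354) had medians under 1 TPM, and their ratios lay within the central 95% of random lists, though the choroid plexus list lay at percentile 0.45 of random lists matched on length. In replicates 1 and 2, Col2a1 had 8.91 and 21.2 TPM, Col11a2 2.95 and 3.76, Col9a1 0.57 and 1.06 and Hapln1 0.69 and 0.57. The choroid plexus genes Kl, Folr1, Ttr and Aqp1 had 1.14 and 0.89, 1.10 and 0.91, 0.84 and 0.36 and 0.16 and 0.69, and Apoa1, Afp, Nppa and Alb, of liver and heart, 6.12 and 5.50, 3.13 and 4.0, 1.91 and 2.14 and 1.85 and 1.51. The remote organ list was fixed as a negative control, and 4 of its 16 members reached 1 TPM in both libraries. Levels of a few TPM therefore do not by themselves show expression by cells of the tube. The neuron list exceeded the meninges list by 7.93 in replicate 1 and 3.31 in replicate 2, the ganglion list by 8.14 in replicate 1 and 4.68 in replicate 2, the Schwann cell list by 7.64 in replicate 1 and 5.99 in replicate 2, and the muscle list by 7.38 in replicate 1 and 7.80 in replicate 2.

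Cell cycle genes were higher and synaptic genes lower in replicate 2 relative to the median gene. All 12 cell cycle genes were detected, 4 of them at least 1.5-fold higher in replicate 2 and none as much lower, with list medians of 12.5 and 19.2 TPM. Pcna had a ratio of 0.943, which turns to above 1 under spike-in scaling, Mcm6 was 1.26-fold [1.18 to 1.34] higher, Cdk1 1.58-fold [1.38 to 1.81] and Ccnb1 1.39-fold [1.25 to 1.55]. The median log2 ratio was 0.50, at percentile 99.96 of random lists. The synapse list had a ratio of -0.39, lower than all 10000 random lists, and 3 of its 15 members were at least 1.5-fold lower, with Syp 1.91-fold [1.82 to 2.00] and Gria2 1.41-fold [1.38 to 1.45] higher in replicate 1. Scaling by the spike-ins instead of by TMM raised every log2 ratio by 0.54 and turned the synapse value to 0.16, so that direction holds only relative to other genes. It multiplies each ratio by 1.46, which turns Gria2 but not Syp. Of 38 lists with a ratio, 14 lay above and 4 below the central 95% of their random lists. With random lists matched on length instead, chosen after seeing the data, these were 13 and 3. The astrocyte, inhibitory transmitter and motor neuron lists then lay within, at percentiles 4.39, 4.87 and 96.92, and the choroid plexus list below.

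**Figure D4:**
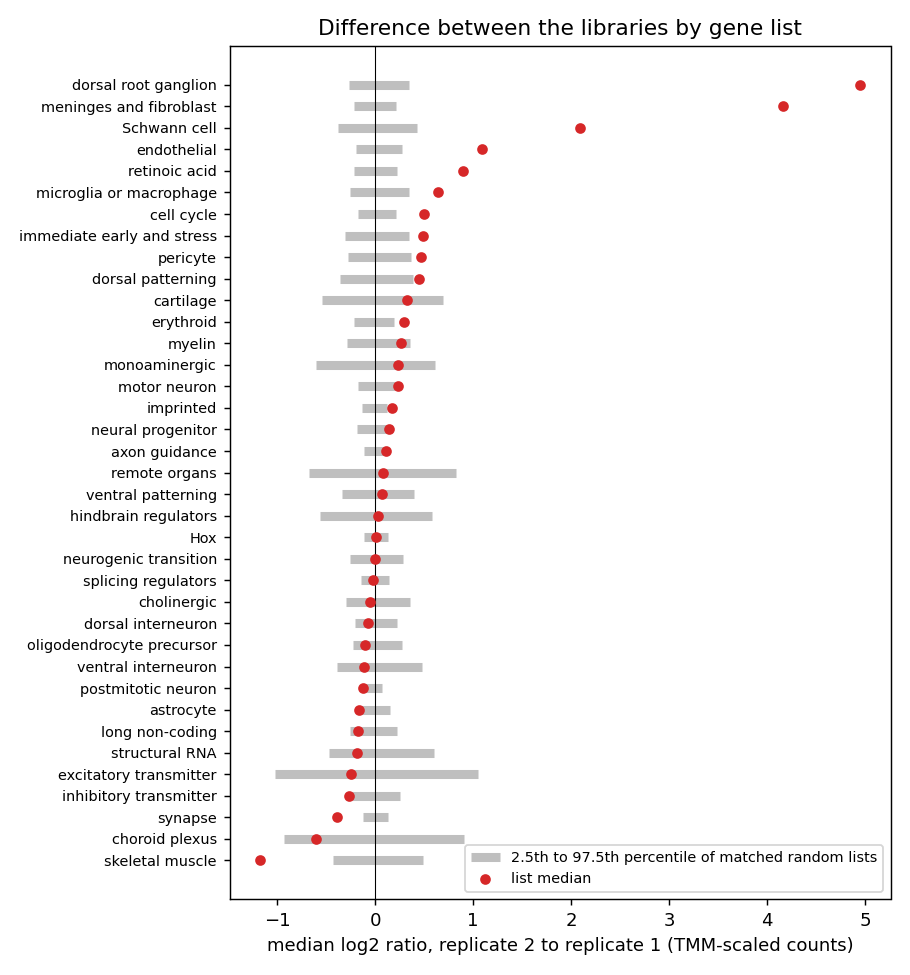
Red points are the median log2 ratio of replicate 2 to replicate 1 (x axis, TMM-scaled counts) of each gene list (y axis, Y-linked genes left out), and grey bars the central 95% of matched random lists. Ganglion and meninges genes reach 4.95 and 4.16 and muscle genes -1.18, and every negative median except those of muscle and choroid plexus genes turns positive when spike-ins set the scale.

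Among 12894 genes with a mean count of at least 100, 472 differed 2-fold or more, 397 of them higher in replicate 2 and 75 in replicate 1. Counting error alone gave 0 such genes in each of 100 Poisson simulations. At such counts a 2-fold ratio lies far outside counting error, so this outcome was nearly fixed in advance. The simulations also left out error from amplified RNA, so they are no measure of technical error. The number was 1527 at a mean count of at least 10, 65.3% of them higher in replicate 2, and 66 at 1000. The largest ratios towards replicate 2 included those of Kdm5d, Eif2s3y, Uty, Ddx3y, Scn10a, 299-fold [102 to 1452], the secreted signal gene Wnt6, 253-fold [44.8 to 10028], Avil and Sfrp5, 62.8-fold [28.5 to 173]. Towards replicate 1 the 10 largest were those of Xist, ENSMUSG00000103508.1, Zfp781, Tsix, Gm10233, Gm4459, Gm5559, Aqp4, ENSMUSG00000096252.1 and Gm21981. The astrocyte water channel gene Aqp4 was 3.94-fold [3.46 to 4.51] higher in replicate 1. Zfp781, with 246 counts against 0, was at least 64.6-fold higher, and ENSMUSG00000103508.1, with 301 against 0, at least 79.0-fold. Gm10233 was 196-fold [34.9 to 7778], Gm4459 7.54-fold [5.16 to 11.4], Gm5559 7.26-fold [4.71 to 11.7], ENSMUSG00000096252.1 3.90-fold [2.82 to 5.50] and Gm21981 3.86-fold [2.93 to 5.16] higher. Zfp781 belongs to a zinc finger family with similar members and Gm10233, Gm4459 and Gm5559 are annotated as processed pseudogenes, so reads may be shared with other genes and these values are uncertain. The 2 genes given by identifier have no symbol in the annotation used.

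The labels name total RNA, so classes without poly(A) tails were summed too. How fully the library protocol, named for Smart-seq, captures such RNA was not tested, so their shares may not be their abundance in the tissue. Protein-coding genes outside the mitochondrial genome took 93.3% ± 0.554 of gene counts (SD, n = 2), mitochondrial genes 2.00% ± 0.0808, ribosomal protein genes 1.34% ± 0.00179, structural RNA genes 0.179% ± 0.0283 and replication-dependent histone genes 0.0256% ± 0.0031. As shares of TPM, which weigh short genes more, the structural RNA genes took 1.65% and the ribosomal protein genes 3.91%. Rn7sk (466 ± 72.1 TPM), Rpph1 (80.2 ± 0.438) and Rmrp (33.7 ± 1.27) led the structural list (median 56.9 ± 0.417), and Terc was under 1 TPM. Spike-ins took 3.31% of all counts in replicate 1 (exact binomial 95% interval 3.31 to 3.32) and 2.29% in replicate 2 (2.29 to 2.30). Over 45 spike-ins with a mean count of at least 100, the SD of the log2 ratio was 0.20, and none of these spike-ins differed 2-fold. It was 0.57 over all genes above the same minimum, which were not matched to the spike-ins in count. Over 62 spike-ins with a mean count of at least 10 the SD was 0.31, against a median of 0.62 over the 50 genes nearest each in count.

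Transcript shares were read for genes on a fixed list. The pyruvate kinase gene Pkm had 83.7% of its TPM in transcript Pkm-202 in replicate 1 and 75.3% in replicate 2, the remainder in Pkm-201. Snap25-201 took 95.7% ± 0.00707 of Snap25 (SD, n = 2) and Nrcam-201 80.0% ± 3.15 of Nrcam. Cdc42-201 took 61.4% and 52.8% of Cdc42, and Dcx-201 63.6% and 52.0% of Dcx in replicates 1 and 2. The leading transcripts of Mapt (Mapt-205, 42.0% ± 0.834), Map2 (Map2-201, 31.6% ± 3.52), Src (Src-202, 43.5% ± 4.15), Nin (Nin-202, 69.3% ± 2.17) and Agrn (Agrn-205, a retained intron, 58.2% ± 4.39) varied by gene, and Ptbp2 had 1 transcript.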

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

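Rows with numeric identifiers, which carry no gene identifier and entered no comparison, held 12 counts in replicate 1 over 6 rows and 14 counts in replicate 2 over 7 rows. They were flagged because data outside the main measurement exceeded the 3 counts that a count of 0 allows. That bound holds for 1 row and not for a sum over all such rows, so passing it carries little weight. There were 26248 such rows per library, and no explanation was tested, technical or biological.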

How the results depend on the processing

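The alternatives of left-out list members, of left-out genes that differed most, of spike-ins alone and of random lists matched on length were chosen after seeing the data, the others before. Of 462 alternative values, 326 stayed within a tolerance. Many of them were fixed or nearly so in advance, so this share is no measure of robustness. Rescaled FPKM is nearly proportional to TPM, and rho over all genes does not depend on the pseudocount. DESeq2 size factors and spike-in scaling each shift every list ratio by a constant. Sign changes numbered 24, all of list ratios, 13 of them under spike-in scaling and 3 of lists outside the central 95% of random lists. The tolerance was 1.5 times for numbers of genes and the coefficient of variation, 0.01 for correlations, 1 SD between the libraries for levels, list differences and shares, 1 SD of random lists for list ratios and 1 log2 unit for sex-linked ratios, and list percentiles had to stay on the same side of the central 95%. Genes detected numbered 16736 at 0.5 TPM, 11125 at 5 TPM, 18783 with posterior mean TPM and 13789 with FPKM, against 15053 in both libraries, 15831 in all in replicate 1 and 15954 in all in replicate 2. Under spike-in scaling, which adds 0.54 to every log2 ratio by construction, the synapse list became 0.16, the inhibitory transmitter list 0.28 and the astrocyte list 0.38, and the cell cycle, Schwann cell, ganglion, meninges and muscle lists 1.04, 2.64, 5.50, 4.70 and -0.63. With deposited TPM, the synapse, Schwann cell, ganglion and muscle lists gave -0.31, 0.95, 4.58 and -0.94. Apart from the smaller ratio of Egr2 in the Schwann cell list, the cause was not tested. Genes past 2-fold numbered 1527 at a mean count of at least 10 and 66 at 1000, as more or fewer genes enter; 65.3% of the former and 84.1% of the main set were higher in replicate 2. Without the sex-linked, ganglion, Schwann cell and meninges members, 449 remained of 472. Only genes on those short lists were left out, so this cannot show how many of the rest are genes of such tissue. The Pearson r was 0.977 with a pseudocount of 0.1 and 0.964 at a mean of at least 1 TPM, where rho was 0.966; rho was 0.956 on TMM-scaled CPM, and the cause was not tested. The coefficient of variation was 0.0732 by DESeq2's median gene-wise dispersion, and the cause was not tested, 0.155 without the 5% of genes that differed most, which lowers it by construction, and 0.0576 over spike-ins. With posterior mean TPM, which is above 0 at 0 counts, Xist had a log2 ratio of -7.30 and the Y-linked sum 6.55. With a pseudocount of 0.1, Hox minus forebrain and midbrain genes was 6.71, inhibitory minus excitatory 5.72, and neuron minus muscle, cartilage and remote organs 8.47, 10.61 and 10.63. With members at 0.1 TPM or more, Hox minus forebrain and midbrain genes was 4.13 and neuron minus cartilage 7.84. With means for medians these were 3.20 and 7.69, inhibitory minus excitatory 2.54, and neuron minus progenitor, muscle and remote organs 3.84, 7.14 and 7.99. Of 15 list differences, 2 had opposite signs in the libraries, so that leaving out replicate 1 turns them. A level or list difference without 1 replicate is the other library's value, within 1 SD by construction and not among the 462, and a correlation, spread or ratio has no value then, and no paired analysis was possible because there is 1 group.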

Other observations

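The tests of counting error, of a lower cord share and of dilution were chosen after the results were seen, and the others before their values were seen, on gene lists partly added after the first results. Imprinted genes had a list median of 94.2 ± 34.1 TPM, led by the long non-coding RNA gene Meg3 (1958 ± 295), Snrpn (886 ± 119), Ndn (791 ± 64.3) and Mest (326 ± 20.9). The growth factor gene Igf2 was 6.5-fold [5.93 to 7.14] higher in replicate 2 and the neighbouring H19 5.06-fold [4.56 to 5.62]. These 2 genes, Hbb-y and Hba-x were picked after their values were seen. The embryonic Hbb-y was 5.38-fold [5.13 to 5.63] and Hba-x 3.45-fold [3.11 to 3.83] higher in replicate 2, whereas the adult-type Hbb-bs, Hbb-bt, Hba-a2 and Hba-a1 had ratios of 0.672, 0.783, 0.834 and 0.916, the last 3 of them above 1 under spike-in scaling. Reads may be shared among globin genes. The erythroid list, led by Hba-a2, Hbb-bs, Hba-a1 and Hbb-bt, had a median of 34.2 TPM in replicate 1 and 129.99 in replicate 2, and a median log2 ratio of 0.29, at percentile 99.72 of random lists.

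Retinoic acid genes had a median of 18.3 TPM in replicate 1 and 57.5 in replicate 2, with Crabp1 (581 and 482), Crabp2 (36.0 and 84.2) and Aldh1a2 (9.50 and 57.5) among the highest, and their median log2 ratio of 0.90 went with that of the meninges list, 4.16. Splicing regulators had a median of 65.8 ± 0.53 TPM, with Rbfox1 (190.2 ± 6.91), Ptbp2 (182 ± 9.29), Celf4 (162 ± 12.2) and Elavl2 (156 ± 28.2) highest. Long non-coding genes had 62.7 ± 2.96, with Malat1 (7794 ± 1538) above Meg3, Snhg11 (697 ± 199.6) and Pantr1 (96.4 ± 3.35). Immediate early and stress genes were low (3.89 ± 0.339; Jun 25.8 ± 8.29, Dusp1 21.8 ± 0.297, Ier2 14.2 ± 4.02, Hspa1a 5.86 ± 0.226), with a median log2 ratio of 0.49, at percentile 99.31 of random lists. The cause was not tested. Pluripotency genes stayed under 1 TPM in all 6 cases, Tdgf1 highest at 0.43 and 0.35.

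The first pattern is the split of sex-linked RNA. Had each library held RNA of embryos of both sexes, Xist and Y-linked genes would reach 1 TPM in both. Xist had 0.05 TPM in replicate 2, and no Y-linked gene exceeded 0.02 TPM in replicate 1, which argues against the explanation that each library holds RNA of embryos of both sexes. A single embryo per library, XX in replicate 1 and XY in replicate 2, is a hypothesis consistent with these values and with the part of the labels that names a single tube, and a pool of embryos of the same sex was not excluded.

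The next pattern is the excess of ganglion, Schwann cell and meningeal genes in replicate 2. Counting error is argued against, since the intervals of 20 of 20 ganglion and meninges members lay above a ratio of 1. It is not excluded, because these intervals treat reads as independent molecules, which reads from amplified RNA are not. The Schwann cell list was not tested for it. A lower cord share that raised every other cell type alike is argued against by the muscle list, whose median log2 ratio was -1.18. Ganglia, nerve and meninges kept on the tube of replicate 2 may account for it, and second sets of genes chosen without their values put fibroblast genes above all 10000 random lists and Schwann cell genes at percentile 99.98, but sensory genes at 35.47, with 2 of the 9 measured members over 2-fold higher in replicate 2, none 1.5-fold higher in replicate 1 and 7 at 1 TPM or more in replicate 1 already. The ganglion part therefore stays open, and sex and litter, which differ between the same libraries, were not tested.

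The last pattern is that cell cycle genes were higher and synaptic genes lower in replicate 2 relative to the median gene. Dilution of cord RNA by carried tissue would lower the dorsal interneuron and synapse lists alike, if the carried tissue expressed neither. The dorsal interneuron list instead exceeded the synapse list by 0.31 in median log2 ratio, beyond a spread of 0.12. Whether carried ganglia also hold RNA of dorsal interneuron genes was not tested, so dilution stays open. Dividing cells in carried tissue were not tested as a source of the cell cycle part. Gene length is argued against, since among random lists matched on length the synapse list lay at percentile 0 and the cell cycle list at 99.97. An earlier stage of the embryo of replicate 2 may account for the pattern, but a list of 9 genes that decline during development (Lin28a, Lin28b, Hmga2, Igf2bp1 and related genes) lay at percentile 85.43, between the bounds set for that test, so it stays open. With 1 library each, stage, sex and litter cannot be told apart.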
